A study of Homo sapiens with 9 samples.

How the data were processed

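RNA was measured in H295R cells, a human adrenocortical carcinoma line that makes steroid hormones. The 9 arrays fall into 3 groups of 3, each from 3 independent experiments per the labels: a vehicle control with 0.1% DMSO, 10 µM 2-OH-BDE47 and 10 µM 2-OH-BDE85, all for 24 h. The series description calls the controls medium alone, whereas the sample labels give DMSO, and the labels were followed. Both compounds are hydroxylated polybrominated diphenyl ethers (flame-retardant derivatives), and 2-OH-BDE85 carries 1 bromine more than 2-OH-BDE47. Per the labels, total RNA was made into biotin-labelled RNA and put on Affymetrix arrays whose probe sets cover the whole genome.

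The authors deposited 1 intensity value per probe set and array, on a linear scale. The probe summary, background correction and normalization are not given in the sources used here. The 54675 probe sets had no missing and no negative values, and values ran from 0.533 to 17430. Array medians ran from 49.5 to 56.3, a range of 0.141 on the log2 scale, and the mean of each array without its top and bottom values ran from 237.9 to 271.7. Between 904 and 1070 values per array were exactly 1. The arrays were taken as already scaled and were not scaled again. Precision is limited by the number of arrays.

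Values were used as log2(value + 16). Of the probe sets, 41091 carried exactly 1 gene symbol, 1801 carried several and 11783 were not named here, including 62 control probe sets. The Entrez identifiers of 41037 probe sets were found in the reference table of gene names, and 0 symbols had to be updated. For each of 19775 genes the probe set with the highest mean was kept. Genes with a mean above the median of all probe sets other than controls (6.10 on the log2 scale, an intensity of 52.5) were tested, which left 12643.

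Differences between groups were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend) over all 9 arrays, with group means only. Each gene had 6 residual degrees of freedom, and the moderation added 7.15. A gene passed when its two-sided p, adjusted by Benjamini-Hochberg over the 12643 genes, was below 0.05. Fold changes are log2 differences of group means, given with the standard error (SE) of the fit or with its 95% interval. A moderated F test asked for any difference among the 3 groups.

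There were 28 pathway lists and 7 lists of cell type markers, all fixed before the data were examined. The pathway lists covered steroidogenesis, cholesterol synthesis, fatty acid synthesis, LXR targets, fatty acid oxidation, ATF4 targets, ER chaperones with the unfolded protein response, aminoacyl-tRNA synthetases, heat shock, NRF2, AhR, xenobiotic metabolism, metallothioneins, p53, DNA replication, G2 and mitosis, apoptosis, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, ribosome biogenesis, immediate early genes, NF-kappaB, type I interferon, autophagy, the proteasome, thyroid and nuclear receptors, and TGF-beta with matrix. Each list was tested against all other genes with camera, a competitive test in limma, at a preset inter-gene correlation of 0.01, adjusted over the 28 lists and 3 comparisons. The same test with the correlation estimated from the arrays, and fry, a test of whether the members move 1 way, stand beside it. Members were counted as having risen or fallen over all genes tested, and again adjusted over the list alone.

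Genes to name were set by a rule made at the same time as the lists. It takes, per comparison, the 10 highest and 10 lowest fold changes among genes past the threshold whose groups do not overlap. It adds up to 4 members with the smallest p of each list past the threshold and of 8 lists always shown, and a set of steroidogenic enzymes whatever their p. List members outside this rule, named where 5 or fewer went against their list or where a sentence says so, were picked after their values were seen.

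Calls shared by both compounds were set against the number that independent calls would give. The correlation of the fold changes was set against 50 simulated draws of unchanged groups that share 3 control arrays, since both comparisons use the same controls. Control probe sets were compared between groups with an exact permutation test, two-sided, whose smallest p for 3 against 3 is 0.1. List medians of interest were set against 10000 random lists matched in 20 bins of mean intensity. After the data were seen, 198 families of at least 8 genes with a common symbol stem were tested with camera, adjusted over families and comparisons.

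Replicate numbers recur in each group, and whether they pair the arrays was checked by correlating deviations from the group means across genes, for which a pair had to exceed 0.1. Same-numbered control and 2-OH-BDE47 arrays correlated at 0.31, 0.72 and 0.52, and same-numbered 2-OH-BDE47 and 2-OH-BDE85 arrays at 0.42, 0.56 and 0.28. Arrays of different numbers reached at most 0.17 and 0.14. The numbers were therefore taken to pair the arrays of these comparisons, and not those of 2-OH-BDE85 and vehicle control. The pairing comes from the values and not from the labels.

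The steps were tested on simulated data made for 2-OH-BDE47 against vehicle control on 12643 genes. Of 250 genes changed at each size, over 5 runs, 7.2% of 1.25-fold, 37.6% of 1.5-fold, 91.6% of 2-fold and 100% of 4-fold changes were recovered. Of 124.8 calls per run on average, 6.6 were of unchanged genes. Each run changed far fewer genes than the 4285 that passed in the data, with noise independent between genes. The recovered shares are therefore not the power of the real comparison.

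Alternatives fixed at the same time as the lists covered the filter, quantile normalization, median centring, the pseudocount, the choice of probe sets, the variance model, array weights, a replicate block, each array left out, a 1.5-fold minimum, a test without moderation, a fit of only the groups compared, the estimated correlation and fry. The test without moderation also used only the arrays of the groups compared. A further 3 were chosen after seeing the data: cyclic loess normalization, and as covariates the level of the poly-A control probe sets and the ratio of the ACTB probe sets at the 3' and 5' ends of the transcript. Probe sets with several symbols or no name were left out of the gene tests because no single gene could be assigned to them. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.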

Results

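Gene expression was measured in 9 cultures of H295R adrenocortical carcinoma cells, 3 kept in 0.1% DMSO, 3 exposed to 10 µM 2-OH-BDE47 and 3 to 10 µM 2-OH-BDE85 for 24 h. The array medians lay between 49.5 and 56.3 intensity units. Across the 12643 genes tested, arrays of 1 group correlated with each other at 0.9706 to 0.9934, and arrays of different groups at 0.9352 to 0.9758. The moderated F test found 5734 genes that differed among the 3 groups. Fold changes below are log2 values ± SE with 3 arrays in each group, and p-values are adjusted values from limma unless a sentence says otherwise. The labels state 3 independent experiments per group, and these p-values weigh differences against the spread between experiments within groups. The fit did not pair arrays, so variation that same-numbered arrays share stays in that spread.

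The first comparison asked which genes respond to 2-OH-BDE47. Most genes tested of the stress response to amino acid shortage and to unfolded protein rose, as did the AhR target CYP1A1, most genes tested of cholesterol and fatty acid synthesis and of cell division fell, and the steroidogenic gene CYP17A1 fell. In total 4285 of the 12643 genes (33.9%) passed, 2479 higher and 1806 lower, and 764 of them changed at least 2-fold. With the replicate number as a block, 5430 genes passed, 3119 higher and 2311 lower, and these include all 4285.

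Of 26 measured targets of ATF4, a transcription factor that is translated under stress, 21 rose and 1 fell with 2-OH-BDE47, and 22 and 1 did so adjusted over the list alone. The list median was 1.64 (camera adjusted p = 2.41e-60, but adjusted p = 0.572 with an estimated correlation). DDIT3, which encodes the stress transcription factor CHOP, rose by 3.72 ± 0.09, from an intensity of 398 ± 30.3 to 5442 ± 288 (SD, n = 3). TRIB3 rose by 3.25 ± 0.13 and asparagine synthetase ASNS by 3.24 ± 0.17. The member that fell was VLDLR, a lipoprotein receptor, by 1.31. ER chaperone and unfolded protein response genes showed 22 of 26 risen and 0 fallen, the same counts adjusted over the list alone, with a median of 0.80 (camera adjusted p = 6.18e-22, and adjusted p = 0.576 with an estimated correlation). XBP1, a transcription factor of that response, rose by 2.62 ± 0.11, the co-chaperone DNAJB9 by 2.06 ± 0.09, and HSPA5, the main chaperone of the endoplasmic reticulum, by 1.11 ± 0.08 to an intensity of 12050. Among 17 aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 14 rose and 1 fell, and 15 and 1 adjusted over the list alone (median 0.80, camera adjusted p = 1.45e-12, and adjusted p = 0.64 with an estimated correlation). SARS1 rose by 1.58 ± 0.10 and GARS1 by 1.51 ± 0.13. EPRS1 fell by 0.46 on the probe set used, while another of its probe sets rose by 1.54, so its direction is not settled.

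Of 7 targets of the aryl hydrocarbon receptor (AhR), a sensor of planar aromatic compounds, 4 rose with 2-OH-BDE47, also adjusted over the list alone, with a median of 0.78 (camera adjusted p = 5.48e-06, and adjusted p = 0.576 with an estimated correlation). CYP1A1, the classic AhR-induced enzyme, had the highest fold change of the rule-named genes at 4.29 ± 0.32, or 19.6-fold, from an intensity of 66.6 ± 13.2 to 1741 ± 885 (SD, n = 3). TIPARP rose by 2.81 ± 0.14, and AHRR, the receptor's repressor, by 1.52 ± 0.22. For 20 NRF2 genes of the oxidative stress response, 9 rose and 1 fell, and 10 and 1 adjusted over the list alone. That list did not pass (camera adjusted p = 0.0819), and it passed with the replicate number as a block (adjusted p = 0.0139), with adjusted p = 0.822 with an estimated correlation.

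Of 19 genes of cholesterol synthesis and SREBP2 targets, 10 fell and 1, STARD4, rose with 2-OH-BDE47, the same adjusted over the list alone, with a median of -0.38 (camera adjusted p = 0.000303, and adjusted p = 0.717 with an estimated correlation). INSIG1, which restrains SREBP processing, fell by 0.98 ± 0.13, lanosterol synthase LSS by 0.73 ± 0.09, and HMGCS1, an early enzyme of the pathway, by 0.54 ± 0.08. Of 13 fatty acid synthesis genes, 8 fell and 1, ME1, rose, the same adjusted over the list alone (median -0.44, camera adjusted p = 0.001, and adjusted p = 0.64 with an estimated correlation). SREBF1, the gene of the transcription factor that drives them, fell by 2.50 ± 0.22, from an intensity of 604 to 92.8, and ACLY fell by 0.46 ± 0.08.

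Steroidogenesis as a list of 23 genes did not pass with 2-OH-BDE47, with 5 members risen and 5 fallen, also adjusted over the list alone (median 0.00, mean -0.03, camera adjusted p = 0.567). CYP17A1, which makes the precursors of cortisol and androgens, fell by 1.14 ± 0.14, from an intensity of 1061 ± 130 to 469 ± 15.5 (SD, n = 3). The androgen sulfotransferase SULT2A1 fell by 0.81 ± 0.18 and the angiotensin receptor AGTR1 by 0.84 ± 0.13. CYP19A1 (aromatase) rose by 0.55 ± 0.19 (adjusted p = 0.0393), which did not pass without control replicate 1 (0.57), without control replicate 3 (0.44) or without 2-OH-BDE47 replicate 2 (0.38). For STAR, which moves cholesterol into mitochondria, the value was -0.14 (95% interval -0.35 to 0.07), for CYP11A1, the first enzyme of the pathway, -0.13 (-0.34 to 0.08), and for HSD3B2 -0.30 (-0.99 to 0.40), and none of these passed. CYP11B1 and CYP11B2 lay below the filter over all arrays and were not tested. With 2-OH-BDE47 the mean intensity of CYP11B1 was 8.95 ± 5.38 against 14.8 ± 2.3 in controls, and that of CYP11B2 30 ± 18.2 against 24.3 ± 5.47 (SD, n = 3).

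Of 43 genes of G2 and mitosis, 26 fell and 0 rose with 2-OH-BDE47, and 31 and 0 adjusted over the list alone, with a median of -0.66 (camera adjusted p = 1.92e-07, and adjusted p = 0.756 with an estimated correlation). The mitotic kinesin KIF11 fell by 1.39 ± 0.24 and the mitotic kinase AURKA by 1.24 ± 0.25. Of 45 genes of DNA replication, 23 fell and 1 rose, and 26 and 2 adjusted over the list alone (median -0.42, camera adjusted p = 5.79e-05, and adjusted p = 0.737 with an estimated correlation). RRM2, which makes the building blocks of DNA, fell by 2.17 ± 0.25, the replication clamp PCNA fell by 0.52 ± 0.08, and CDC6, which licenses replication origins, rose by 1.14 ± 0.16. Of 7 metallothionein genes 6 fell, and 7 adjusted over the list alone (median -0.42, camera adjusted p = 0.00149, and adjusted p = 0.717 with an estimated correlation), among them MT1E by 0.78 ± 0.13. Of 25 proteasome subunits 7 fell and 1 rose, also adjusted over the list alone (median -0.12, camera adjusted p = 0.0247, and adjusted p = 0.737 with an estimated correlation). The proteasome call ended without control replicate 2 (median -0.10) and without 2-OH-BDE47 replicate 1 (-0.11), and also with no variance trend (-0.12).

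Of 18 p53 targets 8 rose and 3 fell with 2-OH-BDE47, also adjusted over the list alone, with a median of 0.10 and a mean of 0.57 (camera adjusted p = 0.0197, and adjusted p = 0.822 with an estimated correlation). GADD45A rose by 3.06 ± 0.19 and SESN2 by 2.41 ± 0.16, and SESN2 is also on the ATF4 list. The 3 that fell, BAX, FAS and TP53I3, promote cell death. Of 17 immediate early genes, whose transcription answers signals quickly, 9 rose and 1, the phosphatase DUSP6, fell, also adjusted over the list alone (median 0.43, camera adjusted p = 0.00507, and adjusted p = 0.737 with an estimated correlation). EGR1 rose by 1.88 ± 0.21 and JUN by 1.58 ± 0.21. ATF3, also on the ATF4 list, rose from a low control intensity of 42.7 to 523, by 2.46 to 3.62 depending on the value added before the logarithm. Outside the lists, the cyclin CCNF fell by 2.27 ± 0.29. The chemokine receptor CXCR4 and the Wnt inhibitor DKK1 fell to low intensities of 33.0 and 36.1, with log2 values from -1.91 to -3.16 and from -1.58 to -2.68 depending on the value added before the logarithm.

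On the 2-OH-BDE47 arrays the ACTB ratio of 3' to 5' probe sets, a sign of RNA integrity, was higher than in controls by 0.24 (exact permutation p = 0.1, the smallest possible). With this ratio as a covariate, chosen after seeing the data, 921 genes passed, 797 of them shared with the 4285, and the median SE rose from 0.16 to 0.307. Of the genes named above these no longer passed: CYP17A1 (-1.02), AURKA (-1.48), KIF11 (-1.42) and PCNA (-0.51), whose fold changes stayed near their size or grew, and RRM2 (-1.61), CDC6 (0.80), AHRR (0.79), EGR1 (0.99) and CYP19A1 (0.00), whose fold changes shrank. The lists of p53 targets and DNA replication did not pass either (medians 0.13 and -0.42). With array weights 8197 genes passed, and with a test without moderation 2683, and without 2-OH-BDE47 replicate 2 the balance was 1952 higher and 1979 lower. Without probe sets of the _x_at and _s_at types, which can match more than 1 transcript, the lists of fatty acid synthesis (median -0.29), p53 targets (0.34), the proteasome (-0.09) and immediate early genes (-0.02, a turned sign) no longer passed, and the metallothionein list, of which 1 of 7 members has another type of probe set in use, could not be tested.

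**Figure D1:**
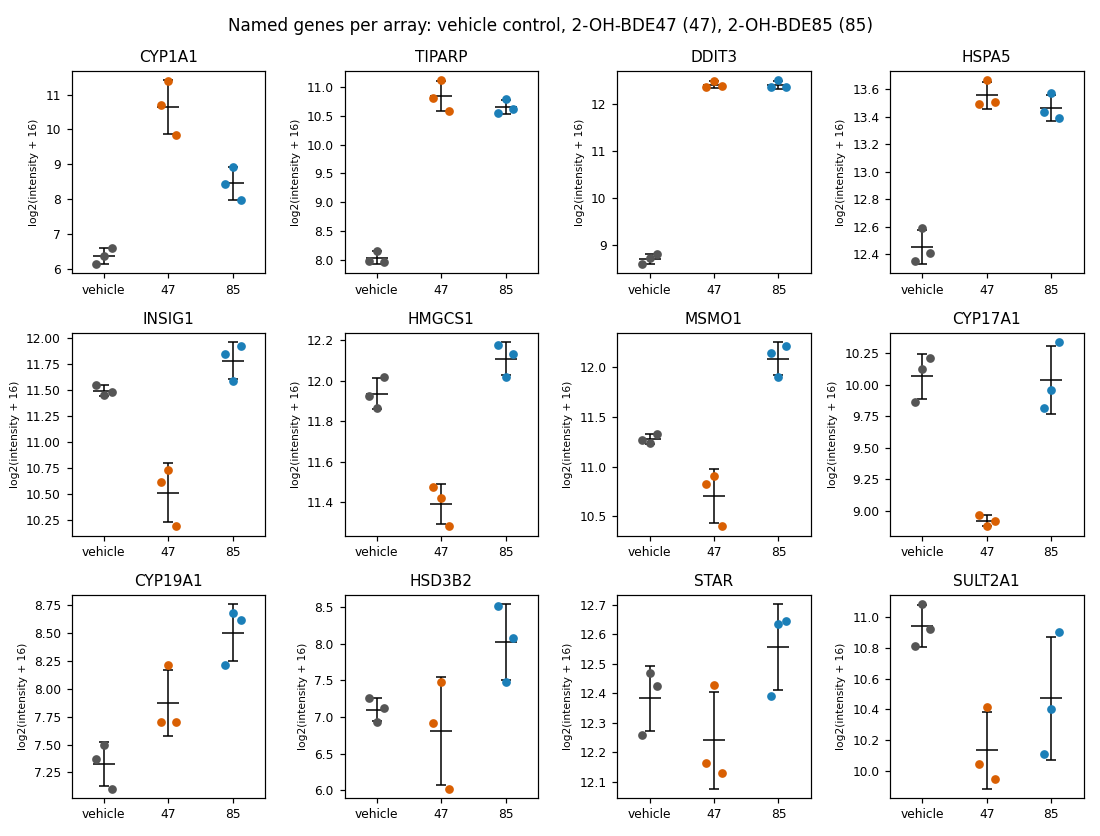
Log2 intensity (log2 of value + 16, vertical axis) of 12 named genes on each of the 9 arrays, by group (horizontal axis), where points are arrays, long bars are group means and short bars mark 1 SD. The CYP17A1 points of 2-OH-BDE47 lie below those of both other groups, and the DDIT3 points of both compounds lie above the controls.

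The second comparison asked which genes respond to 2-OH-BDE85. Most of the ATF4, unfolded protein response and immediate early genes rose, 10 of 43 genes of G2 and mitosis and 17 of 45 of DNA replication fell, and CYP19A1 rose while CYP17A1 stayed near the control intensity. In total 4460 genes (35.3%) passed, 2523 higher and 1937 lower, and 846 changed at least 2-fold. With quantile normalization the balance turned, to 2197 higher and 2824 lower of 5021.

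With 2-OH-BDE85, 20 of 26 ATF4 targets rose and 1 fell, and 21 and 1 adjusted over the list alone, with a median of 1.29 (camera adjusted p = 1.5e-43, and adjusted p = 0.576 with an estimated correlation). DDIT3 rose by 3.73 ± 0.09, PPP1R15A, which resets the block of translation, by 3.00 ± 0.12, and CEBPG by 2.72 ± 0.10, and VLDLR again was the member that fell, by 1.40. Of 26 ER chaperone and unfolded protein response genes 18 rose and 0 fell, and 19 and 0 adjusted over the list alone (median 0.52, camera adjusted p = 1.06e-14, and adjusted p = 0.576 with an estimated correlation). XBP1 rose by 2.72 ± 0.11, HERPUD1 by 1.38 ± 0.07 and HSPA5 by 1.02 ± 0.08, to an intensity of 11310. Of 17 aminoacyl-tRNA synthetases 12 rose and 2 fell, and 13 and 2 adjusted over the list alone (median 0.50, camera adjusted p = 0.000189, and adjusted p = 0.737 with an estimated correlation). YARS1 rose by 1.43 ± 0.14, and the 2 that fell were RARS1 and EPRS1. EPRS1 had a value of -0.61 ± 0.07 on the probe set used, and its direction turned to 0.47 with the mean of its probe sets.

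Of 17 immediate early genes 11 rose and 1, DUSP6, fell with 2-OH-BDE85, also adjusted over the list alone, with a median of 0.85 (camera adjusted p = 2.65e-06, and adjusted p = 0.576 with an estimated correlation). ATF3 rose to an intensity of 793, EGR1 rose by 2.70 ± 0.21 and the orphan nuclear receptor NR4A2 by 2.35 ± 0.20. Without _x_at and _s_at probe sets this list did not pass (median 0.44), nor did DNA replication (-0.25) and oxidative phosphorylation (-0.05), whose call also ended with no variance trend (-0.13). Of 7 AhR targets 4 rose, and 5 adjusted over the list alone (median 0.40, camera adjusted p = 0.00231, and adjusted p = 0.576 with an estimated correlation). TIPARP rose by 2.62 ± 0.14 and CYP1A1 by 2.09 ± 0.32, to an intensity of 346 ± 117 (SD, n = 3).

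Of 43 genes of G2 and mitosis 10 fell and 0 rose with 2-OH-BDE85, and 8 and 0 adjusted over the list alone (median -0.46, camera adjusted p = 0.00102, and adjusted p = 0.822 with an estimated correlation), with CDCA8 at -1.17 ± 0.22 and KIF11 at -1.10 ± 0.24. Of 45 DNA replication genes 17 fell and 4 rose, and 19 and 5 adjusted over the list alone (median -0.24, camera adjusted p = 0.0213, and adjusted p = 0.822 with an estimated correlation). RRM2 fell by 1.28 ± 0.25 and PCNA by 0.49 ± 0.08, while the origin licensing gene CDT1 rose by 0.95 ± 0.13, and CDC6, E2F1 and MCM6 also rose. The replication call ended without control replicate 2 (median -0.18) and without 2-OH-BDE85 replicate 2 (-0.12). Of 43 nuclear genes of oxidative phosphorylation 12 fell and 4 rose, and 13 and 4 adjusted over the list alone (median -0.13, camera adjusted p = 0.00991, and adjusted p = 0.822 with an estimated correlation), with the ATP synthase subunit ATP5MC1 at -0.73 ± 0.09.

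Of 23 steroidogenesis genes 8 rose and 1, AGTR1 at -0.93 ± 0.13, fell with 2-OH-BDE85, and 8 and 2 adjusted over the list alone, and the list did not pass (median 0.19, camera adjusted p = 0.128). CYP19A1 rose by 1.18 ± 0.19, from an intensity of 145.1 to 350.7, and PAPSS2, which makes the sulfate donor, by 1.02 ± 0.15. HSD3B2, which makes progesterone, rose by 0.92 ± 0.32 (adjusted p = 0.0398), a call lost when any control array (0.84 to 1.00) or 2-OH-BDE85 replicate 1 (0.68) or 3 (0.89) was left out. The values of CYP17A1 at -0.03 (95% interval -0.34 to 0.28), CYP11A1 at -0.04 (-0.24 to 0.17), STAR at 0.17 (-0.03 to 0.38) and SULT2A1 at -0.47 (-0.85 to -0.09, adjusted p = 0.0557) did not pass. CYP11B2, below the filter and not tested, had an intensity of 55.5 ± 8.58 with 2-OH-BDE85 against 24.3 ± 5.47 in controls (SD, n = 3). CYP11B1, also not tested, had 12.1 ± 7.38 against 14.8 ± 2.3. Cholesterol synthesis had 5 members risen and 3 fallen of 19, the same adjusted over the list alone, and did not pass (median 0.21, camera adjusted p = 0.429), with MSMO1 at 0.81 ± 0.12 and PMVK at -0.73 ± 0.18. Fatty acid synthesis had 3 risen and 3 fallen of 13, the same adjusted over the list alone (median 0.07, mean -0.14, camera adjusted p = 0.663). NRF2 genes had 6 risen and 2 fallen of 20, the same adjusted over the list alone (median 0.14, camera adjusted p = 0.261), with the cystine transporter SLC7A11, also an ATF4 target, at 1.86 ± 0.19. Among the lowest fold changes of all genes were BLOC1S1 at -2.74 ± 0.16 and the complement regulator CD59 at -2.48 ± 0.19.

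On the 2-OH-BDE85 arrays the ACTB ratio was higher than in controls by 0.07 (exact permutation p = 0.1, the smallest possible), and with it as a covariate 4208 genes passed, 2072 higher and 2136 lower, with 3745 shared with the 4460. With that covariate the DNA replication list (median -0.23) and HSD3B2 (0.51) no longer passed.

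The calls of both comparisons overlapped in direction. Of the genes past the threshold with each compound, 1625 were higher with both and 1079 lower with both, 2704 in all, where independent calls would give 495 and 277. Independence does not allow for the control arrays that both comparisons share. In 50 simulated draws of unchanged groups that share their controls, the highest number of genes past in both was 0. These draws changed no gene and had noise independent between genes, so a count near 0 was fixed in advance. That count cannot show how many shared calls the common controls add. The opposite direction was found for 31 genes, 17 of them higher with 2-OH-BDE47, and all 31 also passed between the compounds. Across genes, which are not independent replicates, the fold changes correlated at r = 0.76 and rho = 0.72. Unchanged groups that share their controls gave a mean r of 0.50 in 50 simulated draws, and the covariance was 0.21 against a simulated 0.015. Without control replicate 1 the shared count was 1784, with the ACTB ratio as a covariate 731, and with array weights 4600.

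**Figure D2:**
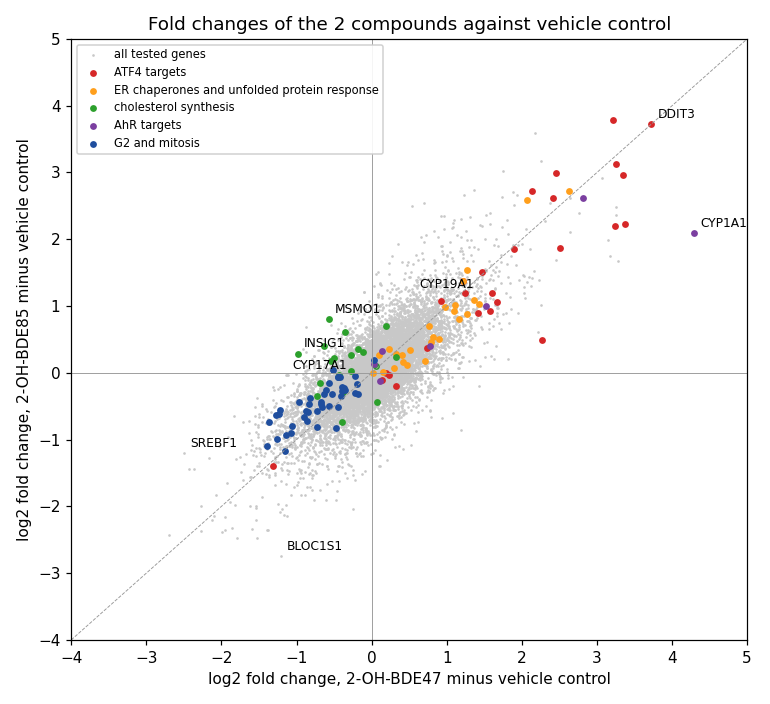
Log2 fold change against vehicle control with 2-OH-BDE47 (horizontal axis) and with 2-OH-BDE85 (vertical axis) for the 12643 genes tested, where each point is a gene and colours mark 5 lists. The ATF4 target DDIT3 lies on the diagonal at 3.72 and 3.73, CYP1A1 lies below it, and cholesterol synthesis genes such as INSIG1 and MSMO1 lie above it.

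The third comparison asked where the compounds, which differ by 1 bromine, differ at the same dose and time. Most of the cholesterol and fatty acid synthesis genes, and 9 of 23 steroidogenesis and 6 of 17 immediate early genes, were higher with 2-OH-BDE85, and CYP1A1, 6 of 17 tRNA synthetases and 5 of 26 ATF4 targets were lower. Of the 12643 genes 2123 (16.8%) passed, 1075 higher and 1048 lower with 2-OH-BDE85, and 231 differed at least 2-fold. With the replicate number as a block, 3407 genes passed, 1644 higher and 1763 lower, and these include all 2123.

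Of 19 cholesterol synthesis genes 13 were higher with 2-OH-BDE85 than with 2-OH-BDE47 and 0 lower, and 13 and 1 adjusted over the list alone, with a median of 0.51 (camera adjusted p = 9.19e-13, and adjusted p = 0.576 with an estimated correlation). MSMO1, a sterol demethylase, differed by 1.38 ± 0.12, with intensities of 2468 in controls, 1678 with 2-OH-BDE47 and 4358 with 2-OH-BDE85. INSIG1 differed by 1.27 ± 0.13 and HMGCS1 by 0.72 ± 0.08. Of 13 fatty acid synthesis genes 7 were higher and 1, GPAM at -0.95 ± 0.15, lower, and 9 and 1 adjusted over the list alone (median 0.44, camera adjusted p = 7.74e-05, and adjusted p = 0.576 with an estimated correlation). Fatty acid synthase FASN differed by 1.02 ± 0.13 and the desaturase SCD by 0.44 ± 0.07.

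Of 23 steroidogenesis genes 9 were higher with 2-OH-BDE85 and 0 lower, and 10 and 0 adjusted over the list alone, with a median of 0.32 (camera adjusted p = 0.000327, and adjusted p = 0.576 with an estimated correlation). CYP17A1 was higher by 1.11 ± 0.14 (95% interval 0.81 to 1.42), with an intensity of 1047 ± 205 against 469 ± 15.5 (SD, n = 3). PAPSS2 differed by 1.01 ± 0.15 and NR4A2 by 1.43 ± 0.20. Calls that ended when single arrays were left out were those of HSD3B2 (1.22 ± 0.32), without 2-OH-BDE47 replicate 1 (1.27) or 2-OH-BDE85 replicate 1 (0.97) or 3 (1.19), and of STAR and CYP19A1. STAR differed by 0.32 ± 0.10, from 0.26 without 2-OH-BDE47 replicate 3 to 0.32 without control replicate 3 where the call ended. CYP19A1 differed by 0.63 ± 0.19, from 0.54 without 2-OH-BDE85 replicate 2 to 0.63 without control replicate 1 where it ended. CYP11A1 did not differ past the threshold, at 0.09 (95% interval -0.11 to 0.30), nor did SULT2A1, at 0.34 (-0.05 to 0.72).

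CYP1A1 was lower with 2-OH-BDE85 than with 2-OH-BDE47, by 2.20 ± 0.32 on the log2 scale, whereas the AhR list of 7 had 0 higher and 1 lower, also adjusted over the list alone, and did not pass (camera adjusted p = 0.123). AHRR differed by -0.52 (95% interval -0.99 to -0.05, adjusted p = 0.122) and passed with the replicate block (adjusted p = 0.0132). Of 26 ATF4 targets 5 were lower and 2 higher, and 10 and 3 adjusted over the list alone (median -0.22, camera adjusted p = 0.0534). The ATF4 list passed with the replicate block (adjusted p = 0.00713), and not with an estimated correlation (adjusted p = 0.822 with an estimated correlation). PCK2, a mitochondrial enzyme of glucose synthesis, was lower by -1.77 ± 0.21 and ASNS by -1.05 ± 0.17, and PPP1R15A and CEBPG (0.59 ± 0.10) were the 2 that were higher. The unfolded protein response list had 4 lower and 1 higher of 26, the same adjusted over the list alone, and did not pass (median -0.15, camera adjusted p = 0.114). DNAJB9 was higher by 0.52 ± 0.09. Of 17 aminoacyl-tRNA synthetases 6 were lower and 0 higher, and 11 and 0 adjusted over the list alone (median -0.33, camera adjusted p = 0.000112, and adjusted p = 0.737 with an estimated correlation), with RARS1 at -0.58 ± 0.11.

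Of 17 immediate early genes 6 were higher with 2-OH-BDE85 and 0 lower, and 8 and 0 adjusted over the list alone (median 0.43, camera adjusted p = 0.00515, and adjusted p = 0.717 with an estimated correlation), with NR4A3 at 0.99 ± 0.18, and with array weights this list did not pass (median 0.32). Of 13 heat shock genes 4 were higher and 0 lower, also adjusted over the list alone (median 0.14, camera adjusted p = 0.00652, and adjusted p = 0.576 with an estimated correlation), with the co-chaperone DNAJB1 at 0.63 ± 0.12. Of 7 NF-kappaB genes 2 were higher, and 3 adjusted over the list alone (median 0.43, camera adjusted p = 0.0291, and adjusted p = 0.576 with an estimated correlation), namely NFKBIA at 0.89 ± 0.19 and TNFAIP3 at 0.53 ± 0.16. The TNFAIP3 call ended without any 1 of the arrays other than 2-OH-BDE47 replicate 2 (0.35 without 2-OH-BDE47 replicate 3 to 0.59 without 2-OH-BDE85 replicate 1), and the list call ended without the filter (median 0.25), with a stricter filter (0.45) and with the mean of probe sets (0.40). Of 43 genes of G2 and mitosis 1, CKS2, was higher by 0.56 ± 0.16, and 0 adjusted over the list alone (median 0.21, camera adjusted p = 0.0416, and adjusted p = 0.858 with an estimated correlation). The CKS2 call ended without 2-OH-BDE47 replicate 1 (0.32) and without 2-OH-BDE85 replicate 2 (0.51) or 3 (0.48). The list call ended without 2-OH-BDE47 replicate 1, where the median was -0.04, without 2-OH-BDE47 replicate 2 (0.30), and without 2-OH-BDE85 replicate 2 (0.18) or 3 (0.05), and also with a stricter filter (0.21), the mean of probe sets (0.26), no variance trend (0.21) and cyclic loess (0.18). DNA replication had 7 higher and 3 lower of 45, and 9 and 3 adjusted over the list alone, and did not pass (median 0.09, camera adjusted p = 0.0589), with CDT1 at 1.04 ± 0.13. NRF2 genes had 2 higher and 3 lower of 20, and 4 and 4 adjusted over the list alone (median -0.13, camera adjusted p = 0.535). Outside the lists, the kinase gene CLK1 was higher by 1.85 ± 0.18 and the enzyme gene JMJD6 by 1.58 ± 0.12.

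Among the genes that changed with either compound, 4182 of 6010 did not pass between the compounds, which does not show that the compounds act alike on them. DDIT3 stood at 3.72 and 3.73, and HSPA5 at 1.11 and 1.02. The median SE of the difference over all genes was 0.16.

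The number of genes called between the compounds rested on few arrays, since 847 passed without 2-OH-BDE47 replicate 1, 1361 without 2-OH-BDE85 replicate 1, 1354 without 2-OH-BDE85 replicate 3 and 3042 without 2-OH-BDE47 replicate 3. A test without moderation called 0 genes here, with 2668 at an unadjusted p under 0.05, against 3854 at that level with limma, and quantile normalization gave 1046 higher and 1691 lower. The ACTB ratio was lower with 2-OH-BDE85 than with 2-OH-BDE47 by -0.17 (exact permutation p = 0.1, the smallest possible), and with it as a covariate 551 genes passed, 502 of them higher. With that covariate the lists of aminoacyl-tRNA synthetases (median -0.11), heat shock (0.24), NF-kappaB (0.06) and G2 and mitosis (0.20) no longer passed, nor did CYP1A1 (-1.20), CYP19A1 (1.02), ASNS (-0.82), GPAM (-0.67), RARS1 (-0.32), NR4A3 (0.74), CKS2 (0.62) and NFKBIA (1.01). Without _x_at and _s_at probe sets fatty acid synthesis (0.23), immediate early genes (0.29), NF-kappaB (0.43) and G2 and mitosis (0.30) no longer passed, and with the mean of each gene's probe sets ASNS (-0.13), CEBPG (0.19) and NFKBIA (0.37) did not.

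**Figure D3:**
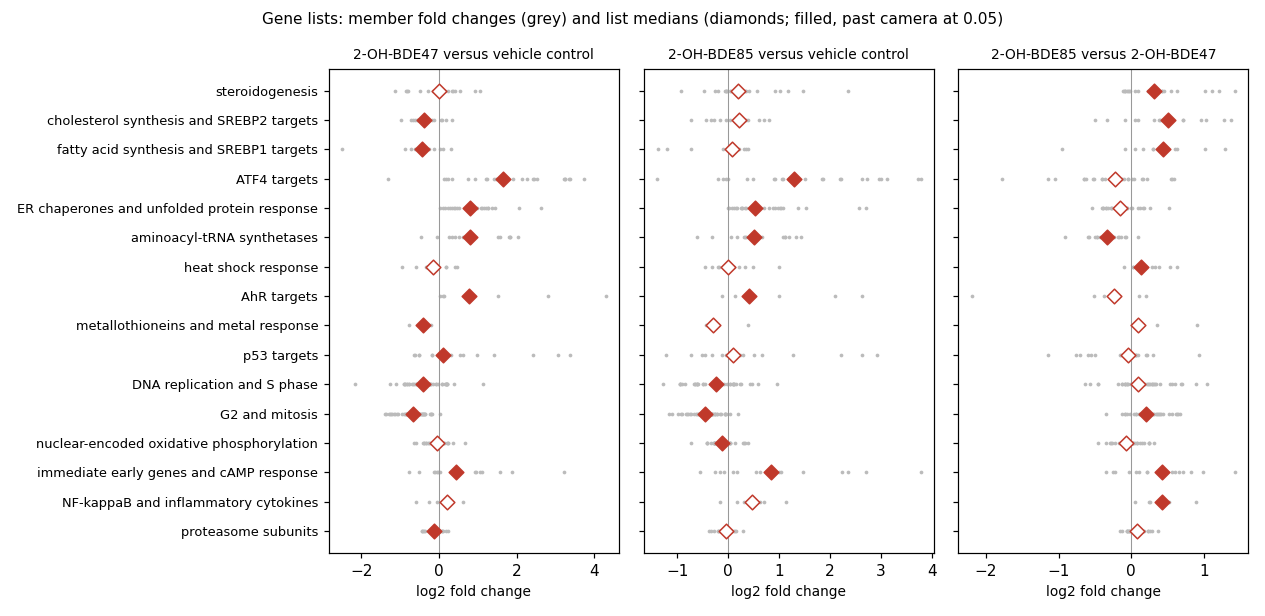
Log2 fold changes (horizontal axis) of the tested members of 16 gene lists in the 3 comparisons, where small grey points are genes and diamonds are list medians, filled where the list passed camera at 0.05. The ATF4 medians lie at 1.64 and 1.29 against vehicle control, and the cholesterol synthesis medians at -0.38 with 2-OH-BDE47 and at 0.51 between the compounds.

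In all, 12 lists passed with 2-OH-BDE47, 8 with 2-OH-BDE85 and 8 between the compounds. Relabelled arrays also reached the counts with 2-OH-BDE85 and between the compounds, as given below. With the estimated correlation camera called 0, 0 and 0 lists, with 3, 1 and 2 at an unadjusted p under 0.05, and fry called 16, 15 and 7. The lists called by fry and by camera were not all the same. Lists that only camera called included G2 and mitosis in each comparison (fry adjusted p = 0.118, 0.267 and 0.594) and DNA replication with 2-OH-BDE85 (fry adjusted p = 0.178). Lists that only fry called included steroidogenesis with 2-OH-BDE85 (fry adjusted p = 0.00916) and NF-kappaB with 2-OH-BDE85 (fry adjusted p = 0.00203). They also included autophagy and lysosome with 2-OH-BDE47 and 2-OH-BDE85 (fry adjusted p = 0.0371 and 0.0442). Of the lists not described above, none passed camera in a comparison against vehicle control, though fry called some of them. Their medians with 2-OH-BDE47 and 2-OH-BDE85 were -0.03 and -0.19 for LXR targets, -0.18 and -0.24 for fatty acid oxidation, -0.56 and -0.32 for xenobiotic metabolism, and 0.15 and 0.08 for apoptosis regulators. They were -0.07 and -0.03 for glycolysis and hypoxia, 0.02 and 0.00 for ribosomal proteins, 0.16 and 0.13 for ribosome biogenesis, 0.21 and 0.05 for type I interferon, and 0.13 and 0.08 for autophagy and lysosome. They were -0.01 and 0.03 for thyroid and nuclear receptors and -0.06 and -0.14 for TGF-beta and matrix. Between the compounds their medians lay from -0.16 for type I interferon to 0.21 for TGF-beta and matrix, and none passed camera. Heat shock genes had 2 risen and 6 fallen of 13 with 2-OH-BDE47 (median -0.15, camera adjusted p = 0.104) and 3 risen and 2 fallen with 2-OH-BDE85 (median 0.00). The metallothioneins (median -0.30), p53 targets (0.10), proteasome (-0.05) and NF-kappaB (0.46) lists did not pass camera with 2-OH-BDE85. Oxidative phosphorylation (-0.06) and NF-kappaB (0.20) did not pass with 2-OH-BDE47, nor did metallothioneins (0.10), p53 targets (-0.04), oxidative phosphorylation (-0.07) and the proteasome (0.08) between the compounds. The sign of the median differed from that of the mean or of the test in lists that did not pass camera. These were glycolysis in all comparisons, LXR targets with 2-OH-BDE85 and between the compounds, NF-kappaB and thyroid receptors with 2-OH-BDE47, fatty acid synthesis, type I interferon and TGF-beta with 2-OH-BDE85, and fatty acid oxidation between the compounds.

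All 9 adrenocortical markers lay above the filter. With 2-OH-BDE47, 2 of them fell, CYP17A1 and the steroidogenic regulator NR5A1 (-0.82), and with 2-OH-BDE85 1, FDX1 (0.40), rose. DLK1 had a mean intensity of 14110 in controls. Of the markers of other cell types, 4 of 7 chromaffin, 4 of 7 fibroblast, 2 of 6 endothelial, 2 of 6 epithelial, 3 of 4 blood and 2 of 5 hepatocyte genes lay above the filter, and 0 changed past the threshold with limma in any comparison. The highest control intensities among them were 582 for EPCAM, 423 for COL1A1, 305 for CHGB and 270 for PECAM1.

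**Figure D4:**
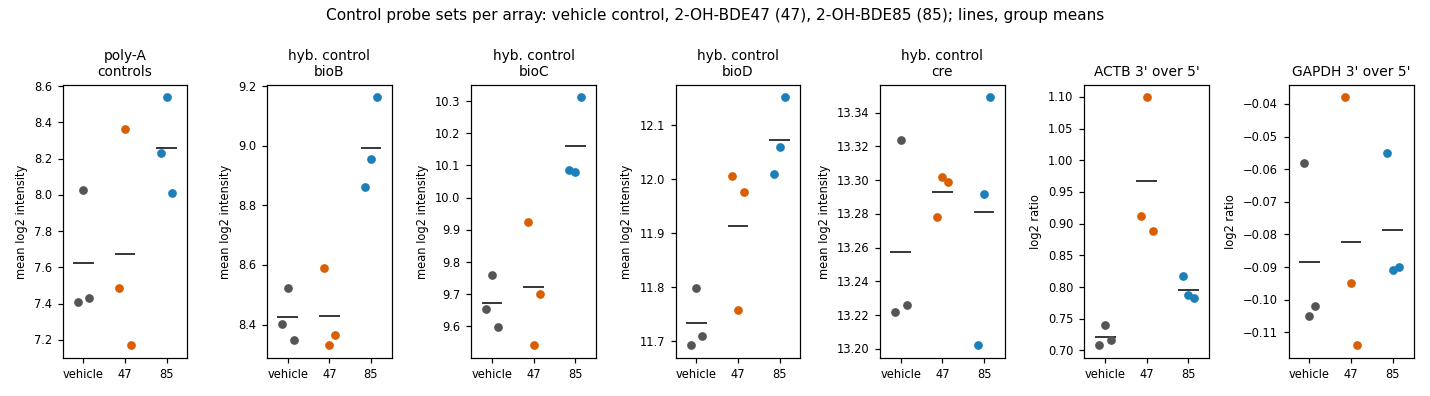
Mean log2 intensity or log2 ratio (vertical axes, each with its own range) of control probe sets on each of the 9 arrays by group (horizontal axis), with lines at group means. The bioB, bioC and bioD controls are higher on the 2-OH-BDE85 arrays, by 0.57, 0.49 and 0.34 against vehicle control, and the ACTB ratio is higher on the 2-OH-BDE47 arrays, by 0.24.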

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

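Tests chosen only after seeing the result were those of a handling batch, of scaling, of splicing factor genes and of splits within replicate numbers, the ACTB ratio as a covariate, and the stricter test of opposite probe sets, which was added once the result at 5% was known.

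Some probe sets for added controls, and the ratio of probe sets at the ends of 1 cellular transcript, differed between groups. Hybridization controls, labelled RNAs added before hybridization, were higher on all 3 arrays of 2-OH-BDE85 than on all 3 of vehicle control, by 0.57 for bioB, 0.49 for bioC and 0.34 for bioD (exact permutation p = 0.1 for each, the smallest possible). The most abundant of them, cre, differed by 0.02 (exact permutation p = 0.7). The poly-A controls were higher with 2-OH-BDE85 than in vehicle control by 0.64 (exact permutation p = 0.2), and the arrays of these groups overlapped. In each group replicate 2 had the highest poly-A level, a mean log2 intensity of 8.028 in controls, 8.363 with 2-OH-BDE47 and 8.537 with 2-OH-BDE85. The log2 ratio of ACTB probe sets at the 3' end to those at the 5' end was higher on all 3 arrays of 2-OH-BDE47, by 0.24, and on all 3 of 2-OH-BDE85, by 0.07 (exact permutation p = 0.1 for each). The same ratio for GAPDH differed by 0.01 with each compound. Among 4105 probe sets with no name or several genes, 555 were higher and 418 lower with 2-OH-BDE47, and 634 higher and 389 lower with 2-OH-BDE85, signals that belong to no single gene here.

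ATF4 targets and ER chaperones were higher with both compounds, on arrays whose ACTB ratio was also higher. With the ratio as a covariate all 4 list tests passed. The medians kept at least 73.8% of their size (ER chaperones with 2-OH-BDE47, 0.59 instead of 0.80). This outcome was predicted if RNA integrity, as this ratio reads it, were not the whole cause, but the test cannot decide it. The ratio hardly varied within vehicle control (SD 0.02) or 2-OH-BDE85 (SD 0.02), so its slope rests mainly on the 2-OH-BDE47 arrays (SD 0.12). With 2-OH-BDE85 the ratio differed from controls by only 0.07, so the covariate could take little away there. Under quantile normalization, median centring and cyclic loess the list medians kept at least 82.7%, which argues against scaling. RNA state, whether or not the ratio reads it, stays open. Since the ratio differs between the groups, the covariate may also take away part of a real response. A response of the cells to the compounds could give this pattern, and no test here told it apart from other differences between the cultures.

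Cholesterol synthesis genes were lower with 2-OH-BDE47 than in vehicle control and higher with 2-OH-BDE85 than with 2-OH-BDE47. Among 10000 random lists matched for intensity, the list median stood at percentile 100 between the compounds (0.51, random lists -0.13 to 0.17) and at percentile 0.03 with 2-OH-BDE47 (-0.38, random lists -0.17 to 0.27), which argues against a distortion that depends on intensity. A handling batch of the 2-OH-BDE85 arrays, which the bioB shift might reflect, cannot account for the median of -0.38 with 2-OH-BDE47, as that comparison does not use those arrays. For the part carried by the 2-OH-BDE85 arrays, treatment and handling cannot be told apart, since each array has the same value of both. A feedback of cellular sterol on this pathway could move its genes together, and it was not tested.

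Some genes had 1 probe set higher and another lower in the same comparison. Probe sets of the _x_at and _s_at types were less frequent where directions opposed. The odds ratio was 0.401 (95% interval 0.22 to 0.725) for 2-OH-BDE47 and 0.346 (0.214 to 0.552) for 2-OH-BDE85. The excess of these types predicted for cross-hybridization was thus not seen. Both types were pooled, so the test does not speak for either alone and cannot exclude cross-hybridization. Opposed directions made up 4.57% of genes with 2 probe sets past the threshold for 2-OH-BDE47 and 6.71% for 2-OH-BDE85, which false calls at the 5% rate allow, but at an adjusted p of 0.001 they still made up 2.35% and 4.38%, which is more than false calls allow. Splicing factor genes were taken by symbols that start with SRSF, HNRNP, RBM, SF3, DDX or DHX and then hold a number. Their odds ratio was 2.74 (0.998 to 6.54) for 2-OH-BDE85, an interval that includes 1, and 5.09 (1.64 to 13.4) for 2-OH-BDE47. Neither value decides the question, since examples of opposed genes had been seen first. The count also missed symbols without a number, such as HNRNPM, opposed with 2-OH-BDE85, and HNRNPC and HNRNPD, opposed with 2-OH-BDE47. Whether alternative transcripts explain these genes stays open.

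Relabelling the arrays gave 10 splits for each single comparison, too few to exclude chance. With the true labels limma called 4285, 4460 and 2123 genes, and the highest of the other splits called 0, 0 and 0, so 1 of 10 splits was as large each time. For the lists the true labels gave 12, 8 and 8 and the highest other split 9, 9 and 13 (1, 5 and 5 of 10 splits as large). The list counts with 2-OH-BDE85 and between the compounds were thus reached under other labels too, and chance could give them. Where the replicate numbers were taken to pair the arrays, with 2-OH-BDE47 against vehicle control and between the compounds, the 3 other splits that part as many pairs called 0 genes each. Over 100 splits into 3 groups the F test gave 5734 genes against a highest other value of 3856, and the genes shared in direction numbered 2704 against 262 with 1 group of each other split drawn as the control, and in each case 1 of 100, the true one, was as large. Of the 36 splits that give each group 1 array of each replicate number, 1, the true one, was as large for both results. The highest other values were 2774 and, taking the highest of the 3 choices of control, 2075. Chance is thus unlikely for these results but not excluded, as 1 of 36 is the lowest share possible here. The arrays of 2-OH-BDE85 and vehicle control also did not meet the rule for pairing by number. The highest of these other splits keep 7 of 9 arrays with their true group.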

How the results depend on the processing

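The settings chosen after seeing the data were cyclic loess and the covariates of poly-A level and ACTB ratio.

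Of 193 results for named genes past the threshold, 119 passed under every alternative scored gene by gene and 74 did not under at least 1. Over these alternatives 4918 values of named genes kept their call, 208 lost it, 38 gained it and 5 reversed. For list medians these numbers were 1924, 35, 49 and 5. The 1.5-fold minimum, the fit of only the groups compared and the test without moderation gave only gene counts and do not enter these numbers. The estimated correlation and fry gave only list counts and do not enter them either. What follows did not hold, and where no reason is given the cause was not tested.

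Without probe sets of the _x_at and _s_at types, 7, 5 and 4 lists passed for 2-OH-BDE47, for 2-OH-BDE85 and between the compounds. The metallothionein list then had too few members to be tested. SFPQ (0.28) and PSMB2 (0.35) with 2-OH-BDE47 and IDI1 (-0.15) and ATP5PD (0.29) with 2-OH-BDE85 reversed, since another probe set stands for the gene, and so did the median of immediate early genes with 2-OH-BDE47 (-0.02). With the mean of probe sets EPRS1 reversed with 2-OH-BDE85 (0.47), and with a stricter filter the median of LXR targets between the compounds (0.43).

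Array weights, whose iteration stopped before its tolerance, gave 8197 genes for 2-OH-BDE47, 5775 between the compounds, 9572 in the F test, 4600 shared and a correlation of 0.723. The replicate number as a block, a pairing read from the values, gave 3407 between the compounds. Between 2-OH-BDE85 and vehicle control, same-numbered arrays correlated at 0.28, 0.48 and 0.02, which did not meet the rule for a pair. There the block gave 5690 genes and also called the p53 list, STAR and SULT2A1. The p53 list had a camera adjusted p = 0.0323 with the block, and from 0.0341 to 0.423 under the other settings of data and fit. Camera with an estimated correlation gave an adjusted p = 0.858, and fry an adjusted p = 0.041. Between the compounds the block also called AHRR, AURKA, CCNA2, CDCA3, SOD2 and the ATF4 list, and with 2-OH-BDE47 the NRF2 list. The block changed no other call of a list or named gene. With the poly-A level as a covariate 3260 genes and 13 lists passed between the compounds, and the correlation was 0.676. With the ACTB ratio 921 genes passed for 2-OH-BDE47, 551 between the compounds and 731 shared, with a correlation of 0.724. The median of ribosomal proteins then reversed for 2-OH-BDE47 (-0.15) and between the compounds (0.10).

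A minimum of 1.5-fold left 2527, 2608 and 1150 genes by construction. A test without moderation, on only the groups compared, gave 2683 for 2-OH-BDE47 and 0 between the compounds, with 2668 at an unadjusted p under 0.05. Fitting only the groups compared with moderation gave 1232 between the compounds. The estimated correlation left 0, 0 and 0 lists with camera, with 3, 1 and 2 at an unadjusted p under 0.05, and fry gave 15 for 2-OH-BDE85.

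Some calls near the threshold ended under further settings. CYP19A1 (with 2-OH-BDE47 and between the compounds), HSD3B2 with 2-OH-BDE85, and STAR, CKS2 and TNFAIP3 between the compounds did not pass without the filter. Median centring ended these calls except HSD3B2, and no variance trend ended these except CYP19A1. The poly-A covariate ended them except CYP19A1 with 2-OH-BDE47, and it ended HSD3B2 between the compounds and the DNA replication list with 2-OH-BDE85 (-0.23). Quantile normalization ended HSD3B2 with 2-OH-BDE85 (0.86).

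Leaving out 1 array at a time, with fewer arrays by construction, gave 3077 to 4725 genes for 2-OH-BDE47, 3159 to 5161 for 2-OH-BDE85, 847 to 3042 between the compounds, 4338 to 6626 in the F test and 1784 to 2962 shared. The correlation ran from 0.706 to 0.797, and lists from 12 to 13, 7 to 9 and 7 to 10. The median of G2 and mitosis between the compounds ran from -0.04, a reversal, to 0.42. Genes near the filter at 6.10 carry little signal over background, and CYP11B1 and CYP11B2 below it were not tested.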

Other observations

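All gene families below, the members singled out and the test of transcripts cleaved by IRE1 were chosen only after seeing the result.

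Some lists that did not pass camera as a whole held genes that changed. Of 19 genes of autophagy and lysosome 7 rose with 2-OH-BDE47 and 6 with 2-OH-BDE85, and 0 fell, with the autophagy gene WIPI1 at 1.72 and 1.65 and GABARAPL1 at 1.29 and 1.27. KLF9, a transcription factor under hormone control, rose by 1.94 and 2.66, and the glycolytic enzyme HK2 by 1.89 and 1.92. Interferon genes went both ways, with MX1 at 1.62 and 1.11 and IFIT1 at -0.73 and -1.37. Of the apoptosis regulators HRK, which promotes cell death, rose by 1.69 and 0.97, and BCL2, which prevents it, fell by 0.87 and 0.98. The lipoprotein gene APOE rose with 2-OH-BDE85 by 1.75.

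Among 198 families of genes with a common symbol stem, camera called 6 with 2-OH-BDE47 and 3 with 2-OH-BDE85, and none passed with an estimated correlation (adjusted p = 1). With 2-OH-BDE47 the protocadherins PCDHB, which are cell adhesion proteins, fell in 11 of 12 members (median -0.76, adjusted p = 0.000329), and the golgins GOLGA rose in 9 of 11 (median 0.67, adjusted p = 0.00116). The SEC genes of secretory transport rose in 13 of 25 (median 0.31, adjusted p = 0.00543) and the ZFAND genes in 4 of 8 (median 0.34, adjusted p = 0.00543). Translation factors EIF rose in 24 and fell in 4 of 50 (median 0.27, adjusted p = 0.0453). DNAJB co-chaperones rose in 5 and fell in 1 of 10 with 2-OH-BDE47 (median 0.40, adjusted p = 0.026) and in 6 of 10 with 2-OH-BDE85 (median 0.58, adjusted p = 0.000338). With 2-OH-BDE85 the ZBTB genes rose in 14 and fell in 4 of 38 (median 0.21, adjusted p = 0.00644) and the KLF genes rose in 8 and fell in 1 of 15 (median 0.71, adjusted p = 0.0453). These directions were the same under quantile normalization, median centring and cyclic loess.

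BLOC1S1 and CD59 were among the lowest genes with 2-OH-BDE85, at -2.74 and -2.48, and stood at -1.21 and -1.79 with 2-OH-BDE47. BLOC1S1 is a known target of IRE1, a sensor of unfolded protein that can cleave transcripts, and cleavage might lower it. Of 6 other reported targets the median with 2-OH-BDE85 was -0.16, at percentile 18.35 of random lists matched for intensity (-0.35 to 0.36), which does not decide the question. SCARA3 (-0.80) and HGSNAT (-0.50) fell with 2-OH-BDE85 while ERP44 rose (0.79).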
